A study of Oryza sativa with 6 samples.

How the data were processed

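Total RNA of rice roots was measured on Affymetrix arrays, with 2 arrays at 0 h, 2 at 6 h and 2 at 24 h after the yeast. Per the labels' protocols, the RNA came from a plant and fungal RNA spin column kit and the biotin-labelled targets from the GeneChip WT Terminal Labeling kit. The authors deposited 1 table of summarised signal values per probe set on a log scale, read here as log2, and per the submitters' processing notes they used Affymetrix Expression Console. The version, the summarisation method, the background correction, the normalization between arrays, any filter and any centring are not given in the sources used here. The base of the logarithm is not stated either, and base 2 was taken because the values run from 0.65 to 13.36 as signals of this array type on a log2 scale do. Every log2 difference and fold printed rests on that reading. The array medians lie between 2.79 and 2.93, so the arrays share a centre but not a spread. No intensity below the summarised level, background signal or detection call was used here, so how far a low signal lies above background is unknown. Control probe sets could not be told from others and stayed among the 41770 tested.

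Probe sets were named through the platform annotation, in which 15299 had 1 gene, 436 several and 26035 none; a probe set with several genes was given no name. Most genes carry a number beginning with LOC, and 14661 of 14662 genes were found by gene number in a RefSeq gene table of the assembly ASM3414082v1, from which symbols were taken for 1948. Coordinates of that assembly are not printed, because the build behind the arrays is not given in the sources used here. Of 607 genes with several probe sets, the probe sets disagreed in sign for 217 at 6 h, 210 at 24 h and 224 between 6 h and 24 h. Gene lists and named genes use the probe set with the highest mean over all 6 arrays.

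Differences were tested with limma 3.58.1 in R 4.3.3. A linear model with 1 mean per time was fitted to the deposited values of all 6 arrays, which leaves 3 residual degrees of freedom, and eBayes added 5.08 prior degrees of freedom. The contrasts were 6 h minus 0 h, 24 h minus 0 h and 24 h minus 6 h, and p-values were adjusted by Benjamini-Hochberg over all 41770 probe sets, with a threshold of 0.05. The word passed refers to this threshold, and rose, fell and changed are used only of genes that passed. Errors are standard errors from the model. Python 3.11.15 was used for the annotation and the plots.

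In all, 42 gene lists were fixed before the data were examined, 36 of pathways and 6 of markers of other tissues or cell types. They were defined by rice locus numbers and words of gene descriptions, which the annotation used here does not hold. They were therefore matched by symbols, with patterns written after the gene tables were seen and before any difference was computed. This left 40 lists with members and 34 with 5 or more, and lists for wall-associated kinases and for the root cap had 0 members. The potassium and sulfate list holds no sulfate transporter, and of 33 markers of dividing cells 17 are kinesins. The nitrate list holds no nitrate or nitrite reductase, and the assimilation list no glutamate synthase or asparagine synthetase. The calcium sensor list holds calcium-dependent kinases, CBL proteins, their kinases and calmodulins. Lists with 5 or more genes were tested with limma's camera at a preset correlation of 0.01, adjusted over the 34 lists, and also with an estimated correlation, with fry and with a rank-based camera. Each list's median was placed among 10000 random lists of the same size matched on mean signal in 20 bins. In the comparison of both times, all 6 arrays, the controls included, were simulated 100 times as unchanged. They were drawn around the control means with the same spread per probe set for every array.

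Genes were named by a rule written before the data were examined. It takes, in each comparison, the 8 largest rises and the 8 largest falls among genes past the threshold with both arrays of one time above both of the other, with free places going to the next by unadjusted p, and up to 4 members of each list with the smallest unadjusted p at 6 h or 24 h. Since most of those genes are known only by number, the same rule was run among genes with a symbol, an addition made after seeing the data, and at most 2 numbered genes per direction are printed. Other genes named in the text are said to have been chosen after their values were seen.

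The alternatives fixed in advance were quantile normalization, centring each array on its median, leaving out the lowest 33.3% of probe sets by mean signal, an intensity trend with robust estimation in eBayes, array weights, a fit to the 4 arrays of the 2 times compared, the replicate number as a block, a fold of at least 2 with adjusted or unadjusted p, 1 probe set per gene, and leaving out each array in turn. Cyclic loess, and quantile normalization with an intensity trend and robust estimation, were added after seeing the data. The labels give replicate numbers, but with 2 numbers per time and nothing that ties them to plants or days they were not used to pair arrays. The labels and the table hold no hybridization or scan batch, so a batch shared by the arrays of a time cannot be told apart from the time.

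The procedure was tested on simulated data built on the 41770 probe sets, with 200 changed probe sets in each of 10 draws. Changes of 2-fold were recovered in 2.69% of cases at 6 h and 2.39% at 24 h, changes of 4-fold in 71.8% and 74.2%, and changes of 8-fold in 99.2% and 99.5%. The mean number of false calls was 9.9 per draw for both comparisons. Lists of 9 and 40 genes shifted by -1 on the log2 scale were called by camera in 5 of 5 draws. That shift is larger than the medians measured for these lists, -0.54 at 24 h and -0.26 at 6 h against 0 h.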

Results

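Roots of 3-week-old rice plants (Oryza sativa, cultivar Swarna MTU7029) were profiled around the addition of Rhodotorula mucilaginosa JGTA-S1, a pigmented basidiomycete yeast. Roots taken at 0 h were the control, and further roots were taken 6 h and 24 h after the yeast was given, with 2 arrays at each of the 3 times and 6 arrays in all. Every array gave a deposited log2 signal for 41770 probe sets, of which 15299 carried 1 rice gene, 436 carried several and 26035 had no gene in the annotation used here. The 14662 genes measured were mostly known by number, and 1948 had a symbol. For arrays it is their number, 2 per time, that limits the precision. The labels do not say that the 2 arrays of a time came from separate plants or pools, so p-values measure the spread between these samples, which may be technical. No roots kept without yeast for 6 h or 24 h are among the 6 arrays, so each difference from 0 h holds the yeast and the elapsed time together.

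Array medians lay between 2.79 and 2.93, but the spread of signal was narrower at 0 h. The SD over probe sets was 1.50 and 1.46 on the control arrays, 1.82 and 1.62 at 6 h, and 1.79 and 1.75 at 24 h. Across probe sets, the 2 control arrays correlated at a Pearson coefficient of 0.868, the 6 h arrays at 0.936 and the 24 h arrays at 0.976. Probe sets are not independent replicates, and these values only describe likeness. The first control array correlated with the treated arrays at 0.871 to 0.888, above its value with the second control array. By the median absolute log2 difference, however, it lay nearer the second control array (0.450) than the treated arrays (0.463 to 0.520). The first 6 h array and the first 24 h array correlated at 0.978. The first principal component, 50.1% of the variance, separated the control arrays from the treated ones, and the second, 20.7%, separated the control arrays from each other. The median SD between the arrays of a time was 0.32 at 0 h, 0.27 at 6 h and 0.17 at 24 h on the log2 scale.

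**Figure D1:**
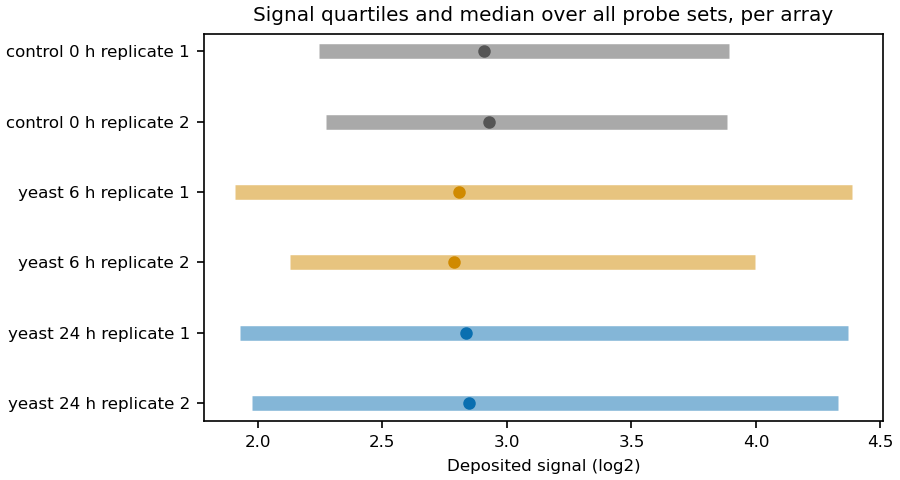
Deposited log2 signal on each of the 6 arrays, with the bar from the lower to the upper quartile over 41770 probe sets and the dot at the median. The control bars run from 2.25 to 3.89 and from 2.27 to 3.88, and the bar of the first 6 h array runs from 1.91 to 4.39.

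The first comparison asked which root transcripts differed between 0 h and 6 h after the yeast. Among genes with a symbol PIP5K, a phosphatidylinositol phosphate kinase, was 8.13-fold higher (log2 difference 3.02 ± 0.40, SE, n = 2 arrays per time). OsCIPK15, a kinase known from the response of rice to low oxygen and sugar, was 6.62-fold higher (2.73 ± 0.34), and OsCDPK17, a calcium-dependent protein kinase, 6.29-fold higher (2.65 ± 0.32). The nuclear matrix constituent proteins OsNMCP1a (2.59 ± 0.31) and OsNMCP1 (2.46 ± 0.31), OSR8 (2.72 ± 0.38), the ribosomal protein RPL10A (2.51 ± 0.40) and the glutaredoxin GRXS11 (2.49 ± 0.29) completed the 8 largest rises. Among genes known by number, LOC4324184 rose 22.2-fold (4.47 ± 0.39) and LOC9266183 rose 14.6-fold (3.87 ± 0.31), while LOC4338522 fell by 2.13 and LOC4342242 by 1.85 on the log2 scale. The homeodomain-leucine zipper factor OsHox28 fell by 1.72 (SE 0.32) and was the only gene with a symbol that fell. The next lower genes with a symbol by unadjusted p did not pass: the response regulator OsRR5 differed by -1.64 ± 0.33 (limma adjusted p = 0.0557), the HSP90 gene HSP81-1 by -1.51 ± 0.35 (0.0765) and the metal-nicotianamine transporter gene osysl3 by -1.62 ± 0.38 (0.0769).

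With limma and an adjusted p under 0.05, 641 of the 41770 probe sets differed at 6 h, 581 of them higher and 60 lower, so that 90.6% were higher. The smallest fold among them was 2.79. They covered 322 genes, 307 higher and 15 lower, of which 271 had no symbol. Unadjusted, 8034 probe sets had a p under 0.05, 4864 higher and 3170 lower, a split that became 3688 and 3284 after quantile normalization and 3408 and 3340 after cyclic loess. Both 6 h arrays lay on the same side of both control arrays for 45.8% of probe sets, against 33.3% by chance. With quantile normalization 81 probe sets passed, and among the genes with a symbol named above OsCDPK17 and GRXS11 kept their calls. All 581 that rose stayed higher with an unadjusted p under 0.05. That was likely beforehand, since they were picked on the same arrays for an adjusted p under 0.05. Without the first control array 2249 probe sets passed, 762 of them lower (66.1% higher), and without the second 1018, 331 of them lower (67.5% higher). Without either 24 h array 81 passed and without either 6 h array 0 did, with the lone array of a time assumed to vary like those of the other times.

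Of 40 gene lists with measured members, 11 held a gene that changed at 6 h, and each of these changes was a rise. Calcium sensors held the largest number in a list of 67 genes, and overall 322 of 14662 genes passed. Of the 67 members 4 rose (OsCDPK17, OsCIPK15, OsCDPK28 at 2.14 ± 0.36 and OsCIPK02 at 1.74 ± 0.33), 0 fell and 63 did not pass. Adjusted over the list alone, 13 were higher and 1 was lower. Camera gave the list an adjusted p = 0.304, and it did not pass. The list median was 0.67, and it lay above the median of all named genes by 0.47 as deposited and by 0.16 after quantile normalization and after cyclic loess. OsCIPK02 was named after its values were seen, since it falls outside the rule for named genes. The 2 control arrays, which stand apart from each other, are the reference of every group described here.

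Other lists held smaller numbers at 6 h. Of 47 auxin genes 3 rose, the Aux/IAA repressors IAA24 (2.39 ± 0.42) and IAA6 (1.54 ± 0.28) and the auxin carrier OsPIN5 (1.67 ± 0.31), and 44 did not pass. Adjusted over the list alone, 6 auxin genes were higher. Of 26 phosphate genes 2 rose, OsPHR2, the central transcription factor of phosphate starvation (1.99 ± 0.30), and OsSPX4, an inhibitor of it (1.90 ± 0.30), and the same number were higher when adjusted over the list alone. Of 20 jasmonate genes 1 rose, the JAZ repressor OsTIFY10a (1.78 ± 0.30), and 3 were higher when adjusted over the list alone. Of 28 cytokinin genes 0 passed, and 3 were higher and 2 lower when adjusted over the list alone.

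Cell wall and growth groups held single changed genes at 6 h, apart from dividing cells. Of 33 markers of dividing cells 2 rose, the kinesins KIN13A (1.95 ± 0.30) and BC2 (1.88 ± 0.30), and 5 were higher when adjusted over the list alone. The 17 kinesins among them, a part not fixed as a list in advance, had a median of 0.61. All 33 markers had a median of 0.21, with 19 reading higher and 14 lower. Of 36 histone and cell cycle genes 0 passed, with a median of 0.03. Of 33 cellulose and wall genes 1 rose, the COBRA-like BC1L6 (1.91 ± 0.35), and 3 were higher when adjusted over the list alone. Of 27 phenylpropanoid genes the 4-coumarate ligase 4CL5 rose (1.72 ± 0.29) and was also the only 1 higher when adjusted over the list alone. Of 21 genes in the list for fatty acids and suberin 19 encode CASP or CASP-like membrane proteins, of which OsCASPL1U3 rose (2.05 ± 0.37), and 2 of the 21 were higher when adjusted over the list alone. RPL10A was the only 1 of 13 ribosomal protein genes to rise, with 2 higher when adjusted over the list alone. OsCIPK15 was the only 1 of 11 hypoxia genes to rise, and 1 was higher and 1 lower when adjusted over the list alone. Against that rise 7 of the 11 read lower, with a list median of -0.58, at percentile 0.01 among random lists matched on signal, although camera did not pass (adjusted p = 0.490). Such extremes were not particular to this list: heat shock genes lay at percentile 0, expansins at 0.02 and calcium sensors at 99.99.

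The listed genes of nitrogen uptake and assimilation did not pass at 6 h, apart from an amino acid carrier. Nitrate and nitrite reductases, glutamate synthases and asparagine synthetases are not in these lists, so the counts do not cover them. Of 8 ammonium transporters, 3 nitrate genes and 6 assimilation genes, 0 passed over all probe sets and 0 when adjusted over the list alone. OsAMT1;2 differed by 0.72 ± 0.32, OsAMT3;2 by 0.87 ± 0.36 and cytosolic glutamine synthetase OsGLN1;2 by 0.47 ± 0.30. Of 2 amino acid and peptide transporters, BAT1 rose (1.84 ± 0.35, limma adjusted p = 0.0498) and OsproT did not pass (1.37 ± 0.34), and both were higher when adjusted over the list alone. Of 13 chitinases and pathogenesis-related proteins, 6 WRKY factors, 10 symbiosis and strigolactone genes and 9 diterpenoid phytoalexin genes 0 passed, and 2 WRKY factors and 1 symbiosis gene were higher when adjusted over the list alone. The chitinase Cht9 differed by 1.04 ± 0.30, OsWRKY76 by 1.23 ± 0.31 and SMAX1L by 1.51 ± 0.32. Of 11 markers of green shoot tissue 0 passed, with a list median of -0.03, and CAB1R differed by -1.06 ± 0.32.

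As a set, 40 heat stress genes, 22 heat shock proteins and chaperones and 18 heat stress transcription factors, ranked lower than other genes at 6 h, although 0 of them passed singly. The median was -0.32 for the former part and -0.05 for the latter. Over all 40 the median log2 difference was -0.26, against 0.20 over all named genes, and 13 of the 40 read higher than at 0 h. The list lay below the median of all named genes by -0.46 as deposited, by -0.51 after quantile normalization and by -0.59 after cyclic loess. HSP81-1 and OsHsp24.1 differed by -1.51 and -0.92, whereas the plastid chaperone CLPB-C and OsHsf-06 differed by 1.37 and 1.53. In camera with a preset correlation of 0.01 the list gave an adjusted p = 0.0424, the only 1 of 34 lists tested to pass, and adjusted p = 0.965 with an estimated correlation. Fry, which asks whether the genes of a list move one way, gave an adjusted p = 0.341 for it, and 0 lists passed in fry at any time. In 16 of the 34 lists the median and camera's direction differed in sign, since camera sets a list against all other genes. Without the first or the second control array the median of this list was -0.15 and -0.10 (adjusted p = 0.0833 and 0.193), without the first or the second 6 h array -0.40 and -0.05 (0.0462 and 0.142), and without either 24 h array the adjusted p was 0.0528.

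The second comparison asked the same of 24 h against 0 h. OsCDPK17 was now the leading gene with a symbol, 8.92-fold higher (log2 difference 3.16 ± 0.32, SE, n = 2 arrays per time). The heat stress factor OsHsf-07 was 8.69-fold higher (3.12 ± 0.47), BC1L6 7.85-fold (2.97 ± 0.35) and the MYB factor MYBAS1 7.45-fold (2.90 ± 0.58). OsCIPK15 (2.81 ± 0.34), PIP5K (2.75 ± 0.40), OSR8 (2.60 ± 0.38) and RPL10A (2.39 ± 0.40) completed the 8 largest rises. LOC4324184 rose 19.5-fold (4.28 ± 0.39) and LOC9266183 rose 19.1-fold (4.25 ± 0.31), while LOC4328351 fell by 2.00 and LOC4341380 by 1.83. The response regulator OsRR5 fell by 1.77 (SE 0.33) and LTD, named for a protein of light-harvesting complex import into plastids, fell by 1.70 (SE 0.30). They were the only genes with a symbol that fell, and the next, the cyclin CYCD4-2, differed by -1.37 ± 0.29 (limma adjusted p = 0.0553). At 24 h OsRR5 and LTD had mean signals of 1.55 and 1.51, below the lower quartiles of the 24 h arrays (1.93 and 1.98). How far such signals lie above background is unknown.

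At 24 h, 925 probe sets passed, 826 higher and 99 lower, so that 89.3% were higher, and the smallest fold among them was 2.64. They covered 452 genes, 436 higher and 16 lower, of which 382 had no symbol. Unadjusted, 8974 probe sets had a p under 0.05, 5694 higher and 3280 lower, which became 3496 and 2827 after quantile normalization and 3234 and 3013 after cyclic loess. In all, 56.4% of probe sets had both 24 h arrays on the same side of both control arrays, against 33.3% by chance. After quantile normalization 24 probe sets passed, 100% of them higher, and OsCDPK17, LOC4324184 and LOC9266183 kept their calls. All 826 that rose stayed higher with an unadjusted p under 0.05, which was again likely beforehand. Without the first control array 2793 probe sets passed, 922 of them lower (67.0% higher), and without the second 1326, 447 of them lower (66.3% higher). Without any 1 of the 4 treated arrays 0 did.

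**Figure D2:**
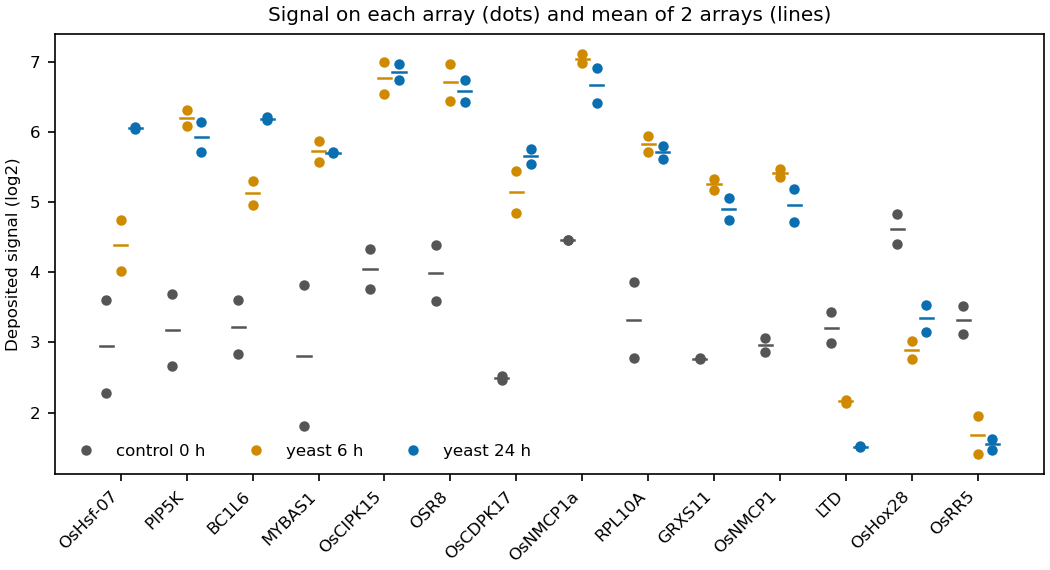
Deposited log2 signal of the genes with a symbol that ranked among the 8 largest passing rises or falls at 6 h or 24 h, with a dot for each array and a line at the mean of 2 arrays. The control dots of MYBAS1 lie apart, at 3.82 and 1.81, and those of OsCDPK17 lie close, at 2.53 and 2.47.

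Calcium sensors again held the largest number at 24 h, while cytokinin genes held the larger share, 4 of 28, and overall 452 of 14662 genes passed. Of 67 calcium sensors 6 rose, 0 fell and 61 did not pass, and adjusted over the list alone 14 were higher and 2 lower. Those that rose were OsCDPK17, OsCIPK15, OsCDPK28 (2.14 ± 0.36), OsCIPK10 (2.00 ± 0.34), OsCDPK21 (2.22 ± 0.41) and OsCDPK18 (1.62 ± 0.32), the last 2 named after their values were seen. Camera gave the list an adjusted p = 0.467. Its median of 0.51 lay above that of all named genes by 0.25 as deposited, by 0.17 after quantile normalization and by 0.15 after cyclic loess.

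Cytokinin response regulators moved in both directions at 24 h. Of 28 cytokinin genes 3 rose and 1 fell, and adjusted over the list alone 5 were higher and 2 lower. The type-A response regulators OsRR10 (1.99 ± 0.33), OsRR4 (1.81 ± 0.36) and OsRR9 (1.72 ± 0.31) rose, whereas OsRR5, of the same type, fell. OsRR5 was dim, with a mean signal of 3.32 at 0 h and 1.55 at 24 h. The signs stayed opposite in every scaling tried, but the fall of OsRR5 lost its call after quantile normalization, where 0 probe sets passed as lower.

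Sugar, metal and clock genes each included 1 that rose at 24 h. Of 33 sugar genes OsSWEET1a rose (2.12 ± 0.39), and 5 were higher when adjusted over the list alone. Of 29 iron genes the metal transporter OsNramp3 rose (1.47 ± 0.29), and 1 was higher and 1 lower when adjusted over the list alone. Of 4 clock genes OsCCA1, a morning-phase factor, rose (2.21 ± 0.28), and 2 were higher when adjusted over the list alone. Of 40 heat shock genes OsHsf-07 alone rose, and it was also the only 1 higher when adjusted over the list alone.

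Several groups held at 24 h the genes that rose at 6 h. Of 26 phosphate genes OsPHR2 (1.63 ± 0.30) and OsSPX4 (1.73 ± 0.30) rose. Of 33 markers of dividing cells KIN13A (1.86 ± 0.30) and BC2 (1.83 ± 0.30) rose, and adjusted over the list alone 7 were higher and 1 lower. The 17 kinesins among them, a part not fixed as a list in advance, had a median of 1.03. All 33 markers had a median of 0.27, with 20 reading higher and 13 lower. Of 36 histone and cell cycle genes 0 passed, with a median of -0.0023. OsTIFY10a (1.56 ± 0.30) rose among 20 jasmonate genes, 4CL5 (1.66 ± 0.29) among 27 phenylpropanoid genes and IAA24 (2.10 ± 0.42) among 47 auxin genes. Adjusted over the list alone, 2 jasmonate genes, 1 phenylpropanoid gene and 1 auxin gene were higher. RPL10A was the only 1 of 13 ribosomal protein genes to rise and OsCIPK15 the only 1 of 11 hypoxia genes, with 4 and 1 higher when adjusted over the list alone. The hypoxia list had a median of -0.26, at percentile 0.03, and a camera adjusted p = 0.467, while the phenylpropanoid list lay at percentile 0. Of 33 cellulose and wall genes BC1L6 and BC1L9 (1.89 ± 0.29) rose, and the same number were higher when adjusted over the list alone.

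The remaining 26 of 40 lists held 0 changed genes at 24 h. Of 8 ammonium transporters 0 passed, with OsAMT3;2 at 1.35 ± 0.36 and 1 member higher when adjusted over the list alone, and of 3 nitrate and 6 assimilation genes 0 passed by either adjustment. BAT1 differed by 1.35 ± 0.35 and did not pass over all probe sets. Of 11 green shoot markers 0 passed, with a list median of -0.01. As a set, the 9 diterpenoid phytoalexin genes ranked lower than other genes, with a median of -0.54 and 7 of 9 below their 0 h level, although 0 of them passed singly. OsKO4 differed by -1.38 ± 0.41, OsKSL7 by -0.81 ± 0.36, OsCPS2 by -0.80 ± 0.35 and CYP76M5 by 0.34 ± 0.29. Camera gave an adjusted p = 0.0444 for this list, the only 1 of 34 to pass, with adjusted p = 0.801 with an estimated correlation and 0.119 in fry. Its adjusted p was 0.111 after quantile normalization, 0.342 and 0.0752 without the first or the second control array, and 0.120 without the first 24 h array. The median and camera's direction differed in sign for 16 of the 34 lists.

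**Figure D3:**
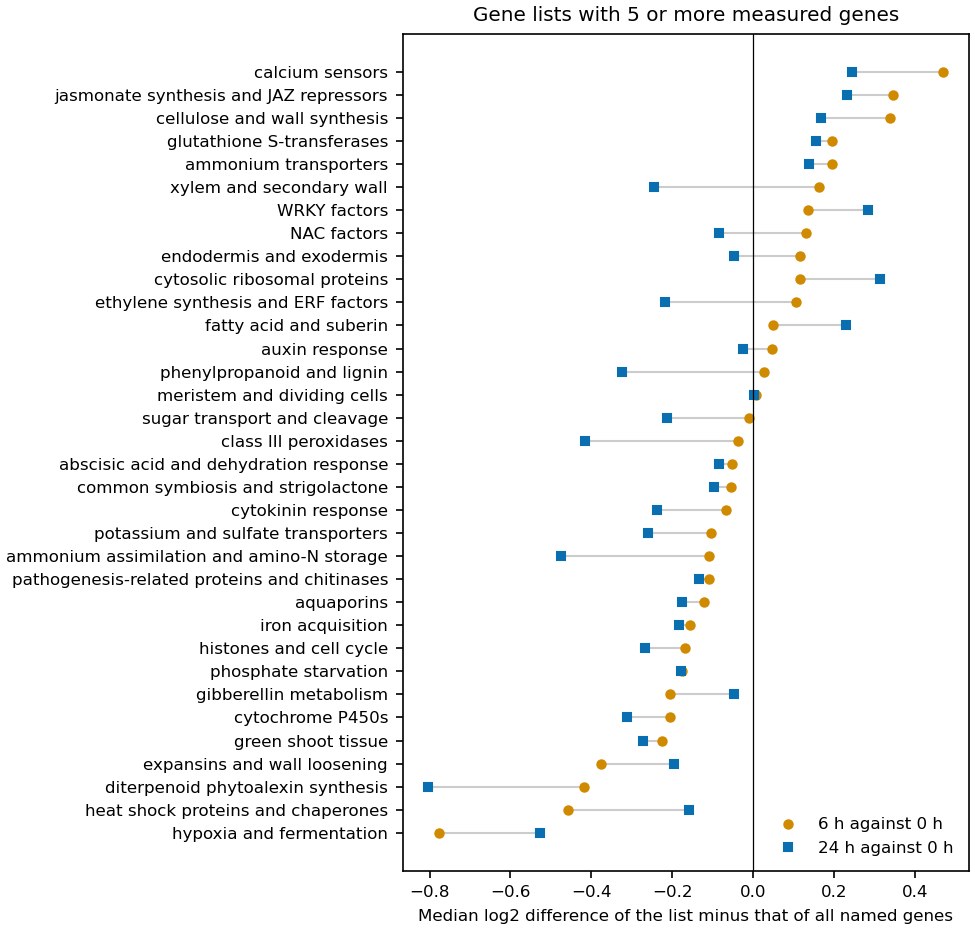
Median log2 difference from 0 h of each of the 34 gene lists with 5 or more measured genes, minus the median of all named genes, at 6 h (circles) and 24 h (squares). Calcium sensors lie at 0.47 and 0.25, and the diterpenoid phytoalexin list at -0.42 and -0.80.

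The third comparison set 24 h against 6 h and asked whether the roots changed further. Heat shock genes stood among the genes with a symbol that read higher at 24 h, and 0 of them passed. OsHsp24.1 differed by 1.85 ± 0.33 (SE, n = 2 arrays per time), OsHsf-07 by 1.68 ± 0.47 and OsHsf-24 by 1.27 ± 0.30. The inositol phosphate kinase OsITPK3 differed by 1.48 ± 0.34 and the clock gene OsPRR37 by 1.37 ± 0.38. Transport and assimilation genes read both ways: the potassium transporter OsHAK22 differed by 1.21 ± 0.29, and OsHAK5 by -1.16 ± 0.36, the potassium channel OsAKT1 by -0.91 ± 0.31, OsGLN1;2 by -0.97 ± 0.30 and OsAMT1;2 by -0.80 ± 0.32. These did not pass either. Of 24 potassium transporters and channels 14 read higher at 24 h, of 8 ammonium transporters 4 and of 6 assimilation genes 3.

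In limma 0 of 41770 probe sets passed between 6 h and 24 h, with a smallest adjusted p of 0.990. Unadjusted, 1097 probe sets had a p under 0.05, 734 higher and 363 lower, and 32.7% had both arrays of one time above both of the other, against 33.3% by chance. On simulated arrays of equal spread, with the dimmest probe sets left unchanged, 75.7% of 4-fold and 3.43% of 2-fold changes were recovered in this comparison. Smaller differences were thus mostly not detectable there. A gene that passed at 24 h and not at 6 h is therefore not shown to differ between these times.

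Among the lists, 2 of 34 passed in camera between 6 h and 24 h. The 9 diterpenoid phytoalexin genes ranked lower at 24 h (median -0.51, adjusted p = 0.0270) and the 40 heat shock genes ranked higher (median 0.21, 28 of 40 higher, adjusted p = 0.0270). For both lists the adjusted p was 0.945 with an estimated correlation. Adjusted over the list alone, 0 diterpenoid genes passed, 1 heat shock gene was higher, and 2 of 4 clock genes were higher. In 10 of the 34 lists the median and camera's direction differed in sign. Both lists had an adjusted p of 0.103 after quantile normalization. Without the first or the second 6 h array the median was -0.44 and -0.41 for the diterpenoid list (adjusted p = 0.220 and 0.211) and 0.44 and 0.12 for the heat shock list (0.426 and 0.0839). Without the first 24 h array it was -0.23 for the diterpenoid list (0.321), and without the second 0.30 for the heat shock list (0.191).

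The changes at 6 h and 24 h were largely shared. Of the probe sets that passed, 489 did so at both times in the same direction, 456 higher and 33 lower, and 0 in opposite directions. They covered 235 genes, 38 with a symbol, among them PIP5K, OsCIPK15, OsCDPK17, OsCDPK28, OsPHR2, OsSPX4, OsTIFY10a, KIN13A, BC2 and 4CL5. A further 152 probe sets passed at 6 h alone and 436 at 24 h alone, and the direct test of 24 h against 6 h passed for 0 of them. Independent lists would share 11.5 higher and 0.142 lower probe sets. Simulated unchanged groups set against shared control arrays, also simulated, gave a mean of 0.2 calls at 6 h and 0.25 at 24 h, too few for the number they shared to be informative. The log2 differences correlated at 0.859 across probe sets, against 0.501 in the simulation, and their covariance was 0.454 against 0.0753, a difference of 0.379. The same sign was seen for 81.6% of probe sets, against 66.7%. With 2 control arrays a split would leave a single array on each side, so part of the excess may come from the shared controls. The simulation gave every array the same spread per probe set, whereas the measured median SD between arrays was 0.32 at 0 h, 0.27 at 6 h and 0.17 at 24 h. The simulated values may therefore be too low for what noisier shared controls produce, and the size of the excess is not settled. After quantile normalization 23 probe sets were shared, without the first or the second control array 1811 and 804, and without any 1 of the 4 treated arrays 0.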

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

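In both results below a gene list stood apart between 24 h and 6 h in camera, a test chosen before the data were examined; the tests of time of day and of dim signal were chosen after the results were seen.

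The 40 heat stress genes, 22 heat shock proteins and chaperones (median log2 difference 0.23) and 18 heat stress transcription factors (0.21), ranked higher at 24 h than at 6 h, with a joint median of 0.21 and a camera adjusted p = 0.0270 (0.945 with an estimated correlation, 0.455 in fry). The difference was not confined to the second 6 h array, which stands apart from the other treated arrays. Against the first 6 h array alone 65% of members read higher at 24 h, compared with 44.6% of all genes, 2.60 binomial standard errors above it. Against the second 75% did, compared with 62.7% of all genes, 1.61 such errors above it. These errors take the genes as independent, and the list was picked on a contrast that holds both 6 h arrays, so neither value is independent support. The camera call was lost without the second 6 h array, where the median shrank to 0.12, so that array may contribute. It was also lost without the first 6 h array, where the median grew to 0.44. Time of day stays open: against 0 h the list at 24 h lay at -0.16 relative to all named genes (-0.32 after quantile normalization) with a camera adjusted p = 0.467, but OsCCA1 differed by 2.21 ± 0.28 and all 4 clock genes read higher at 24 h (median 1.00), so 0 h and 24 h need not be alike in clock phase. A passing response to the yeast at 6 h may equally account for the values and cannot be told apart from time of day without untreated roots at 6 h.

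The 9 diterpenoid phytoalexin genes ranked lower at 24 h than at 6 h, with a median of -0.51 and a camera adjusted p = 0.0270 (0.945 with an estimated correlation, 0.291 in fry), and had a median of -0.54 at 24 h against 0 h. At a mean signal of 2.91 the list's median at 24 h against 0 h lay at percentile 0.55 among 10000 random lists matched on signal. Brighter lists lay lower still, phenylpropanoid genes (mean signal 5.15) at 0 and hypoxia genes (5.71) at 0.03. The diterpenoid list was also picked on these same arrays, so its percentile does not decide whether dim signal is the source. Without the lowest 33.3% of probe sets by signal the 7 members left had a median of -0.40 (quartiles -0.69 and 0.02, against -0.80 and -0.04 for all 9). The camera call was then lost (adjusted p = 0.0742), as it was after quantile normalization with a median of -0.32. The difference from 0 h was not confined to a single 24 h array. On each at least 8 of the 9 members had a difference from the 0 h mean below the median of all genes. Without the first or the second 24 h array the list median was -0.46 and -0.51. Both arrays were set against the same 0 h mean and the list was picked on these arrays, so this likeness was likely beforehand. The median stayed at -0.38 and -0.61 without the first or the second control array. The camera call was lost without the first 24 h array and without either control array. Against 6 h a single 24 h array stays open, with a median of -0.23 without the first. The estimated correlation of the members was -0.10, so their regulation together is not what ended the call, and with that setting camera uses only the residual degrees of freedom of the 6 arrays. A lower defence output after the yeast is an untested hypothesis, which phytoalexin levels in roots kept with and without yeast to 6 h and 24 h could decide, and elapsed time may equally account for the values.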

How the results depend on the processing

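Cyclic loess, and quantile normalization with an intensity trend, were chosen after seeing the data. No named gene or list that passed reversed its direction under any alternative run, and sign changes of differences that did not pass were not counted as reversals. Between 24 h and 6 h, 0 probe sets passed under every alternative with an adjusted p. The cause of the moves below was not tested.

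Of the 641 probe sets that passed at 6 h, quantile normalization left 81, all of them among the 641. Centring on the median gave 1146, the intensity trend with robust estimation 1062, array weights 187, a fit to only the 4 arrays compared 81, cyclic loess 119, and quantile normalization with the trend 274. With an unadjusted p and a fold of at least 2 the number was 5178. Of 925 at 24 h, quantile normalization left 24, all among the 925, array weights gave 1502, only 4 arrays 0, cyclic loess 52, quantile normalization with the trend 175, and the unadjusted p with the fold 6042, against 497 between 6 h and 24 h. Of 37 named genes called at 6 h, 5 kept their call under quantile normalization and 8 under cyclic loess; of 41 at 24 h, 6 and 8 did. The 489 probe sets shared by both times became 23 and 46.

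Leaving out 1 array at a time gave 0 to 2249 at 6 h, 0 to 2793 at 24 h and 0 to 1811 shared. The highest values came without the first control array. The lowest came at 24 h and for the shared number without any single treated array, and at 6 h without either 6 h array. Every fit without 1 array leaves 2 residual degrees of freedom, so this does not set the lowest values apart from the highest.

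Of the lists, 1 passed camera at 6 h, 1 at 24 h and 2 between 24 h and 6 h. At 6 h, 2 passed after quantile normalization, 2 without the dimmest probe sets and 2 after cyclic loess, and 0 passed with an estimated correlation or in fry. At 24 h, 0 passed after quantile normalization, without the dimmest probe sets, after cyclic loess, with an estimated correlation, in fry or in the rank-based camera. Between 24 h and 6 h, 0 passed after quantile normalization, after cyclic loess, with an estimated correlation, in fry or in the rank-based camera, while 3 passed without the dimmest probe sets. Leaving out 1 array gave 0 to 2 lists at 6 h, 0 to 1 at 24 h and 0 to 2 between the times.

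The replicate number as a block gave 384 probe sets at 6 h, 570 at 24 h and 298 shared, and changed no list call. Deviations of equally numbered arrays from their group means correlated across probe sets at 0.047 between 0 h and 6 h, 0.033 between 0 h and 24 h and 0.155 between 6 h and 24 h, and with 2 numbers this does not show pairing. No measure of background was used here, so no limit from signal over background can be given.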

Other observations

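The tests of a single control array and of untreated roots, and the genes named in the next paragraph, were chosen after the results were seen.

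Among genes outside the lists, picked singly and with no test of a shared function, the protein phosphatases OsPP2C39 (log2 difference 2.46 ± 0.33 at 6 h and 1.96 ± 0.33 at 24 h) and OsPP2C15 (1.63 ± 0.30 and 1.89 ± 0.30) rose at both times, and OsPP2C28 rose at 6 h (2.06 ± 0.37). The SnRK2 kinase OsSAPK9 rose at 24 h (1.86 ± 0.35) and stood at 1.81 ± 0.35 at 6 h, where it did not pass (limma adjusted p = 0.0504). Precursors of phytosulfokine, a growth peptide, rose at 24 h in PSK2 (1.93 ± 0.29) and PSK5 (1.54 ± 0.29). The sucrose phosphate synthase OsSPS1 rose at both times (2.24 ± 0.31 and 1.67 ± 0.31), as did the small GTPase OsRac5 (1.84 ± 0.32 and 1.66 ± 0.32). The Dicer gene OsDCL4 (1.73 ± 0.35) and the DNA glycosylase DNG701 (1.60 ± 0.31), which act in small RNA production and DNA demethylation, rose at 24 h.

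The clock gene OsCCA1 had mean log2 signals of 4.32 at 0 h, 5.62 at 6 h and 6.53 at 24 h, and OsPRR37 had 3.29, 3.19 and 4.56. Of the 641 probe sets that passed at 6 h, 306 had no single named gene, 262 higher and 44 lower, and of 925 at 24 h 457 had none, 374 higher and 83 lower.

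Most probe sets that passed against 0 h read higher after the yeast, 90.6% at 6 h and 89.3% at 24 h, and at an unadjusted p under 0.05 the excess shrank with the scaling, from 4864 higher and 3170 lower at 6 h to 3688 and 3284 after quantile normalization and 3408 and 3340 after cyclic loess. The narrower spread of signal on the control arrays therefore stays open for that wider excess. For the rises that passed, quantile normalization, which gives every array the same spread, kept a median of 86.9% of the log2 difference at 6 h (quartiles 78.2% and 96.1%) and 82.5% at 24 h (73.2% and 91.2%). Cyclic loess kept 76.7% and 70%. Both scalings thus left most of these differences. Those probe sets were picked for folds of at least 2.79 and 2.64, while the upper quartiles of the arrays lay between 3.88 and 4.39. A large share kept was therefore likely beforehand and does not decide whether the narrower spread contributed. Most calls still ended after quantile normalization. Over the 581 probe sets that rose at 6 h the median difference went from 2.10 to 1.89 and its SE from 0.33 to 0.31. The prior degrees of freedom fell from 5.08 to 3.55, and the median p in limma went from 0.000252 to 0.000809. Which of these ended the calls was not tested. A single control array was not decided, since fits without either hold 1 array at 0 h: at least 66.1% of calls were higher there, and the share fell because lower calls rose from 60 to 762 and 331 at 6 h while higher calls rose from 581 to 1487 and 687. The yeast itself and the elapsed time cannot be told apart with 0 arrays of untreated roots at 6 h or 24 h, and a batch shared by the control arrays, for which the sources used here give no record, may also contribute.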
